A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

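Total RNA from 4 yeast samples was measured on 4 Agilent yeast gene expression arrays in 1 colour, with 2 arrays at 0 min and 2 arrays 90 min after 6 nM estradiol. All 4 arrays sat on 1 slide and were scanned in 1 session. The labels give the numbers 1 and 2 in both groups and the series describes biological replicates, but what a shared number marks is not given in the sources used here. The protocols differ on the optical density at estradiol addition, with 0.5 in one and about 1 in another.

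The deposited scanner files hold, per the file headers, spot intensity in arbitrary units extracted with Agilent Feature Extraction 10.7.3.1, and the processed intensity is its background-subtracted, detrended signal. The deposited value table holds log2 values, 1 per probe, and the submitters' processing notes name limma without a version or steps. In a check of that table, 6256 probes were matched on each array, and its values correlated with log2 of the scanner signal at r = 0.9995 to 0.9998 across probes of 1 array, with slopes of 1.01 to 1.039. The table's column medians were 11.65 to 11.67. It lay closest to quantile-normalised log2 median signal, with median gaps of 0.0079 to 0.0105 and largest gaps of 0.69 to 0.76, and whether a background was subtracted is unknown. It was not centred per gene. Changes in the table correlated at r = 0.988 over genes with those computed here, and 4518 calls were shared in direction.

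Each array holds 13048 spots, of which 12512 measure yeast probes, 2 spots each, and 536 are controls. The scanner files were used for the main results. Log2 processed signal was taken relative to the 75th percentile of the yeast spots of each array, and the spots of a probe were averaged, leaving out those the scanner software marked as non-uniform or as population outliers (3 to 10 per array). A probe was tested if it was well above background on both arrays of at least 1 group, which kept 6175 probes and removed 81. Probe names were updated by locus tag (5748 probes) or RefSeq accession (17), and 491 kept the name in the file. A gene with several probes was represented by its brightest, which gave 6144 genes. The array design was built on sacCer2, an older assembly than that of the gene table, so genes are given by name and not by position. Median background was 20.5 to 21 against a median signal of 2969 to 3697, and the 75th percentile lay at 8084 to 9694.

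The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over probes and a threshold of adjusted p under 0.05. The prior carried 4.46 degrees of freedom beside 2 residual ones. The median gap between replicate arrays was 0.066 and 0.069 log2, about that between duplicate spots of 1 array (0.066 to 0.073), so the p-values rest on a small spread. All 4700 called genes had groups that did not overlap, and 12 of them had only a bound in one group. Gene lists were compared with all other genes by camera, at a preset correlation of 0.01 and with an estimated correlation. Whether the members of a list move one way on balance was tested with fry, which makes no comparison with other genes. Except where stated otherwise, the lists, tests and alternatives were fixed before the data were examined. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

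The named genes followed a rule. It took MSN2, MSN4 and the strain markers, then the 15 largest rises and 15 largest falls among called genes whose 90 min arrays both lay on one side of both 0 min arrays. From each list it took up to 4 called members with the largest absolute change, or 2 where none passed. Other genes were picked after their values were seen. Some genes that the rule takes are not reported here.

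Alternatives were scaling on the median, quantile normalization, no scaling between arrays, scaling on spike-in probes, normexp background correction with an offset of 50, and the deposited value table. Further ones were no filter or a filter on all arrays, a replicate block, leaving out each array, a trended or robust prior, the mean of a gene's probes, thresholds of 0.01 and 0.1, a log2 change of at least 1, and treat at 0.5. Normexp was run on median spot signal in place of the planned mean signal, which was not used here. A planned test for stress response elements in promoters was not run, since it needs a genome sequence.

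The pipeline was tested on simulated data for this comparison, with 6144 genes. Of 50 genes shifted at each size, 22 (44%) were recovered at a log2 change of 0.25, 50 at 0.5, 50 at 1 and 49 (98%) at 2. Of 5924 unchanged genes, 20 (0.34%) were called. The shifted list was called and 0 of 33 unshifted lists were. Most simulated genes were unchanged, and their noise was independent between genes. In the data most genes were called and list members can move together, so these rates may not carry over.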

Results

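Transcript levels were measured in the budding yeast Saccharomyces cerevisiae, in a strain labelled BY4741, a common laboratory background derived from S288C. The cells carried Msn2A6 under the control of estradiol. Msn2 is a zinc finger activator of general stress genes that protein kinase A keeps out of the nucleus, and the A6 allele is a form insensitive to that kinase. Cultures of 50 ml grew in rich glucose medium at 30 °C, and total RNA was taken either from untreated cells, at 0 min, or 90 min after 6 nM 17β-estradiol was added. Each group held 2 arrays, which the series describes as biological replicates, and each array measured 1 sample in 1 colour. Of 6256 yeast probes, between 6151 and 6191 per array were well above background, and no spot was saturated. The replicate arrays of a group correlated at r = 0.9990 at 0 min and r = 0.9985 at 90 min over probes, against 0.9587 to 0.9591 between groups. The number of arrays, 2 per group, limits the precision.

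The comparison asks which transcripts differ 90 min after Msn2A6 induction. After 90 min, genes of stress protection, glycogen and trehalose metabolism, antioxidant defence, autophagy and galactose use were higher, as were genes of peroxisomal fatty acid oxidation except with spike-in scaling, where their median was -0.22. Genes of ribosome production, amino acid, purine and sterol synthesis, cell cycle progression and histones were lower. These groups passed a test against other genes at a preset correlation between genes, but had adjusted p = 0.27 to 0.42 with an estimated correlation. The largest rises reached 193-fold for GRE1 and 155-fold for SIP18, and the largest fall was 21.6-fold, for the reading frame YMR173W-A. Among 6144 genes tested, 1860 rose and 2840 fell (limma, adjusted p under 0.05), and 1444 did not pass. At least 2-fold changes were found for 548 genes that rose and 238 that fell. There was no untreated culture at 90 min, so the comparison covers estradiol, Msn2A6 and 90 min of further growth together. The median gene had a log2 change of -0.13 on the main scale, -0.32 with no scaling between arrays and -0.58 with scaling on spike-in controls. The split moved with it, from 39.6% of calls risen to 26.7% (1288 risen, 3532 fallen) and 15.4% (745 risen, 4090 fallen). In those 2 settings an offset shared by all genes of an array enters each gene's test as if it were separate noise. The spike-in signal, relative to the 75th percentile, differed by 0.24 log2 between the 0 min arrays. The counts in those settings are therefore uncertain. Changes are given on the main scale, relative to the 75th percentile of each array. Spike-in scaling lowers each change by 0.45 on the log2 scale, which turns the sign of smaller rises, among them those of GLK1, CAM1, HHO1, CLN3, SPO12, SPL2, HMG2 and DDR48.

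**Figure D1:**
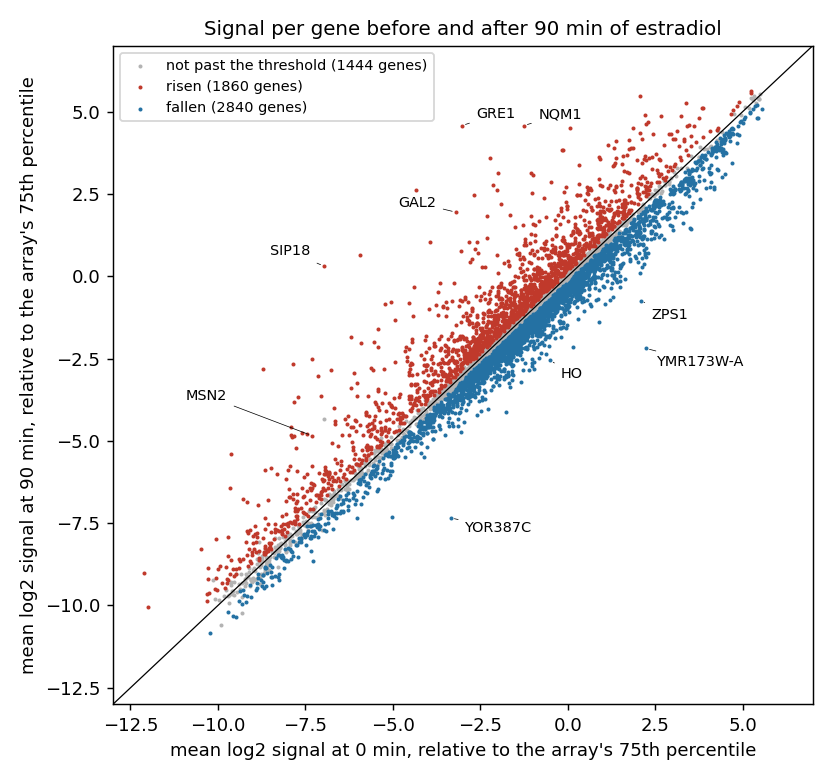
Mean log2 signal of each tested gene at 90 min (vertical) against 0 min (horizontal), both relative to the array's 75th percentile and over 2 arrays; the diagonal marks equal signal. Red points are the 1860 genes that rose and blue points the 2840 that fell, and GRE1, with a log2 change of 7.60, stands farthest above the diagonal among the labelled genes.

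MSN2 itself (YMR037C) gave a log2 signal of -7.31 ± 0.06 (SD, n = 2) at 0 min and -4.84 ± 0.16 at 90 min. Its log2 change of 2.47 ± 0.09 (SE) corresponds to 5.55-fold and passed the threshold (adjusted p = 1.34e-06). The probe was well above background on all 4 arrays, and it cannot separate the induced allele from the chromosomal gene. The signal was low at both times, so the size of the change is uncertain. That size was 1.71 after a normexp background correction and 1.82 in the deposited value table. MSN4 (YKL062W), which encodes a close relative of Msn2, rose by 0.48 ± 0.06 on the log2 scale (1.39-fold, adjusted p = 0.000576). That rise was 0.02 with spike-in scaling, where it no longer passed (adjusted p = 0.9).

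The strain marker genes were measured because they report on the background of the strain. HIS3, LEU2, MET17 and URA3, which serve as auxotrophic markers, were all well above background on the 4 arrays. LEU2 fell by 0.91 ± 0.05, HIS3 fell by 0.86 ± 0.06 and MET17 fell by 1.08 ± 0.06 on the log2 scale. LYS2, of lysine synthesis, fell by 1.83 ± 0.10, and HO, the mating-type switching endonuclease gene, fell by 2.05 ± 0.06. URA3 was the 1 member that rose, by 0.31 ± 0.06, and its change was -0.14 with spike-in scaling. The list of 6 was lower than other genes (camera, adjusted p = 0.033), with adjusted p = 0.28 with an estimated correlation.

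The gene with the largest rise was GRE1 (YPL223C), a hydrophilin gene of osmotic and desiccation stress, at 7.60 ± 0.06 on the log2 scale (SE, adjusted p = 1.41e-08). SIP18 (YMR175W), another hydrophilin gene, followed at 7.28 ± 0.06, and SPG4, a gene of stationary phase, at 6.95 ± 0.08. The rise of NQM1, the minor transaldolase, was 56.8-fold, and that of FMP16 was 56.5-fold. SLZ1, a gene of sporulating cells, rose 36.6-fold, PAI3, an inhibitor of vacuolar proteinase A, 35.3-fold, and CPP3 35.1-fold. POT1, the peroxisomal thiolase, rose 31.7-fold and GND2, the minor phosphogluconate dehydrogenase, 30.4-fold. The galactose permease gene GAL2 rose 35.7-fold and the galactokinase gene GAL1 24.9-fold. The transcript model TC21215 rose 95.9-fold, and the dubious reading frames YDR491C and YLR428C rose 58.6-fold and 27.5-fold. By the rule that picked them, both arrays at 90 min lay above both at 0 min for all 15 of these genes. After normexp background correction the log2 change was 6.46 for SIP18, 4.09 for YDR491C, 3.95 for SLZ1 and 3.73 for YLR428C, against 7.28, 5.87, 5.19 and 4.78 on the main scale. In the deposited value table it was 4.80 for YDR491C, 4.46 for SLZ1 and 4.12 for YLR428C. In total 180 genes rose and 10 fell at least 4-fold.

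The largest falls led with YMR173W-A, at a log2 change of -4.43 ± 0.07 (SE, adjusted p = 6.38e-08). This frame overlaps DDR48, a stress gene whose log2 change was 0.40 ± 0.06. YOR387C fell 16-fold (SE 0.31 on the log2 scale), with a wide replicate spread (SD 0.77 at 0 min) and log2 changes of -4.55 to -3.45 when single arrays were left out. ZPS1, a gene induced by low zinc, fell 7.1-fold, ADH4, an alcohol dehydrogenase, 5.08-fold, and ZRT1, the high-affinity zinc transporter, 3.91-fold. AAH1, the adenine deaminase, fell 4.89-fold, and CTP1, the mitochondrial citrate carrier, and VEL1 each fell 4.86-fold. In lysine synthesis, LYS20 fell 4.3-fold and LYS9 4.07-fold. BIO5 and BIO3, of biotin uptake and synthesis, fell 3.85-fold and 3.79-fold. FET3, the multicopper oxidase of iron uptake, fell 3.72-fold, HO 4.15-fold and YDR222W 3.65-fold. By the rule that picked them, all 15 had both 90 min arrays below both 0 min arrays. After normexp background correction the log2 change was -2.91 for YOR387C and -1.51 for VEL1, against -2.28 for VEL1 on the main scale.

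**Figure D2:**
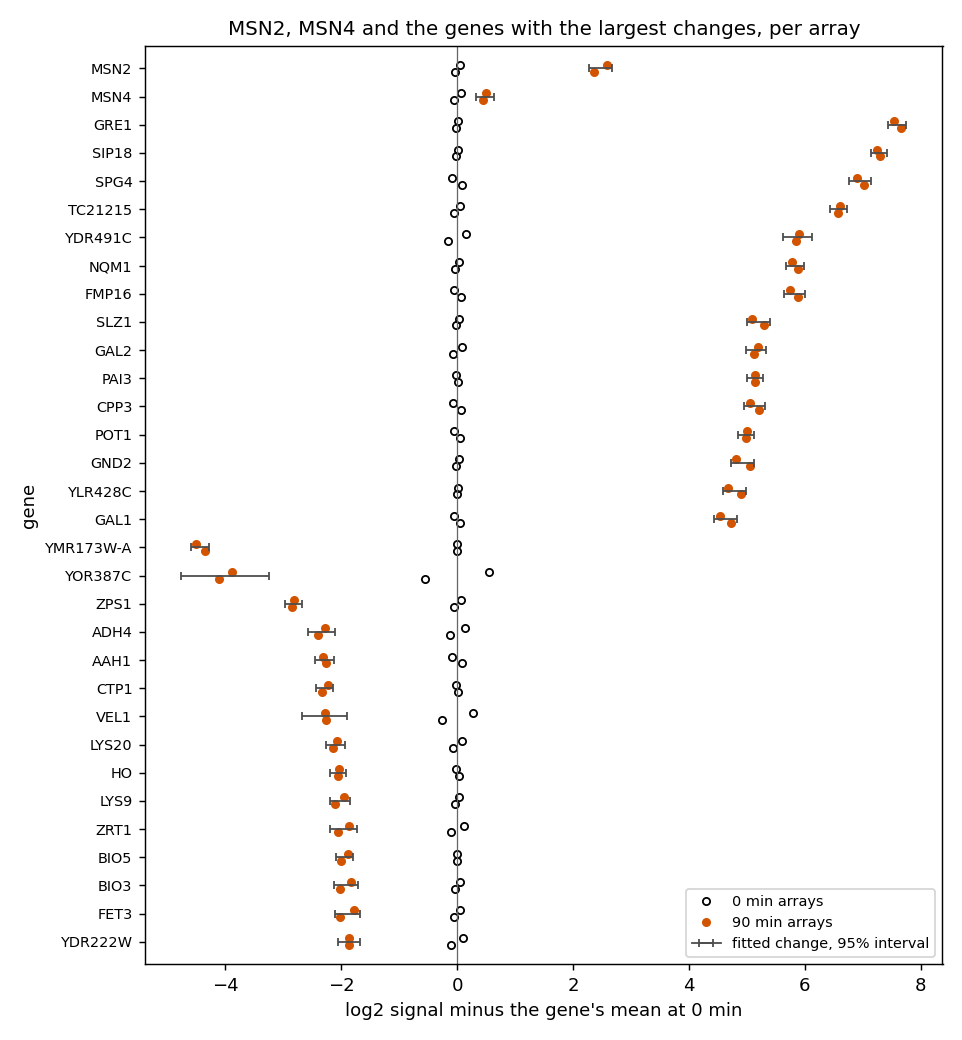
Log2 signal on each array minus the gene's mean at 0 min, for MSN2, MSN4 and the 15 genes with the largest rises and the 15 with the largest falls; open points are the 0 min arrays, filled points the 90 min arrays, and bars the fitted change with its 95% interval. The 90 min points of GRE1 lie near 7.60, and the interval of YOR387C, -4.76 to -3.24, is the widest drawn.

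Gene lists fixed before the data were examined were then tested as groups against all other genes with camera, at a preset correlation of 0.01. Of 34 lists, 26 passed, 10 upward and 16 downward. With an estimated correlation, none passed (limma camera, 0 lists at adjusted p under 0.05, and 3 at unadjusted p under 0.05). That version rests on the 2 residual degrees of freedom of this design and so has little power. A miss there does not tell whether a list shifted. By fry, which tests whether the members of a list move one way on balance, 33 lists passed. No scaling and spike-in scaling shift all genes of an array alike, so they do not move a list against other genes. The camera test weighs each change by its spread, so its p-value can still differ under those scalings. Members of a list that moved against its majority, or that missed the threshold, are named in most lists where 5 or fewer did so, and those outside the rule for named genes were picked after their values were seen. Counts adjusted over the list alone equalled those over all genes except where both are given.

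Genes of the general stress response that are known or likely to carry the stress response element rose almost throughout. Of 40 measured, 39 rose and HSP78, a mitochondrial chaperone gene, fell by 0.25 ± 0.07 on the log2 scale. The median log2 change was 1.87, and 28 members rose at least 2-fold. Besides GRE1 and SIP18, FMP16 rose by 5.82 ± 0.07 and PAI3 by 5.14 ± 0.05. The list was higher than other genes (adjusted p = 9.3e-17), with adjusted p = 0.27 with an estimated correlation.

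In trehalose and glycogen metabolism, 17 of 20 genes rose, with a median of 1.23. The glycogen branching enzyme gene GLC3 rose 7.44-fold, the glycogen phosphorylase gene GPH1 5.26-fold, the glycogenin gene GLG1 4.86-fold and the debranching enzyme gene GDB1 4.4-fold. PIG2 fell by 1.15 ± 0.08 and PGM1, the minor phosphoglucomutase, by 1.22 ± 0.06, while GLG2 had a log2 change of 0.02 ± 0.06. As a group they were higher than other genes (adjusted p = 1.6e-06), with adjusted p = 0.28 with an estimated correlation.

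Antioxidant enzyme genes rose in 21 of 25 cases, with a median of 0.93. The peroxisomal catalase gene CTA1 rose 7.4-fold, the cytosolic catalase gene CTT1 6.17-fold, the glutathione transferase gene GTT1 6.61-fold and the peroxiredoxin gene TSA2 4.18-fold. GTT2 fell by 0.31 ± 0.05 and GPX2 by 0.61 ± 0.06, and TRX1 (0.09 ± 0.06) and DOT5 (-0.02 ± 0.06) did not pass. The list was higher (adjusted p = 2.6e-07), with adjusted p = 0.28 with an estimated correlation. Chaperone genes split, with 10 of 24 risen and 8 fallen. The inducible Hsp70 genes SSA4 and SSA3 rose 18.6-fold and 9.73-fold, the small heat shock gene HSP26 9.47-fold and SSE2 2.77-fold. The Hsp70 genes SSA1, SSA2, SSA3 and SSA4 are similar in sequence, so their single signals are uncertain. The chaperone median was 0.09, and it was -0.10 with no scaling and -0.36 with spike-in scaling. Those scalings lower all genes alike, so a lower p-value there is not a rise of the list against other genes. The list did not pass (adjusted p = 0.061). It passed upward with no scaling (adjusted p = 0.017), spike-in scaling (0.0049), quantile normalization (0.044) or an intensity trend (0.045), and without replicate 1 at 0 min or replicate 1 at 90 min (adjusted p = 0.039 in each).

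In central carbon metabolism the lists moved unevenly. Of 23 glycolysis and fermentation genes, 14 fell and 5 rose, with a median of -0.45, and the list did not pass the test against other genes (adjusted p = 0.18). HXK2, the main hexokinase gene on glucose, fell 2.44-fold and ENO1 3.19-fold, and PFK27 fell 2.22-fold. HXK1, the hexokinase gene of poor carbon sources, rose 3.09-fold, and PDC6 (1.08 ± 0.06), PYK2 (0.67 ± 0.05), PFK26 (0.46 ± 0.06) and GLK1 (0.26 ± 0.06) rose in log2. ADH1 (0.15 ± 0.07), PDC1 (0.05 ± 0.07), TDH1 (-0.03 ± 0.08) and FBA1 (-0.08 ± 0.07) did not pass. In the pentose phosphate pathway, 4 of 11 genes rose, the minor isozyme genes NQM1, GND2, TKL2 (16-fold) and SOL4 (4.16-fold). Another 6 fell, among them GND1 (-1.39 ± 0.07), TAL1 (-0.66 ± 0.06) and TKL1 (-0.52 ± 0.05), and ZWF1 had a change of 0.10 ± 0.07. Its median was -0.23 and its mean 1.20, and the group test, upward, did not pass (adjusted p = 0.53). With spike-in scaling the same test gave adjusted p = 2.6e-05, at a median of -0.69. That scaling lowers all genes alike, so it did not move the list against other genes.

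Glyoxylate cycle and gluconeogenesis genes rose in 14 of 20 cases, with a median of 0.52. The carnitine acetyltransferase gene CAT2 rose 14.5-fold, the mitochondrial aldehyde dehydrogenase gene ALD4 4.29-fold, the glucose-repressed alcohol dehydrogenase gene ADH2 4.06-fold and the carnitine carrier gene CRC1 3.46-fold. ALD6 (-1.19 ± 0.06), CIT2 (-0.95 ± 0.06) and YAT2 (-0.32 ± 0.06) fell, and MLS1 (0.07 ± 0.09), ADY2 (0.05 ± 0.08) and MDH3 (0.05 ± 0.06) did not pass. Together the members were higher than other genes (adjusted p = 0.00038), with adjusted p = 0.28 with an estimated correlation. Of 21 genes of fatty acid oxidation and peroxisomes, 13 rose and 2 fell. POT1 and CTA1 led, the import receptor gene PEX18 rose 3.89-fold, and its relative PEX21 fell 2.63-fold. The list passed upward (adjusted p = 0.0033), also with spike-in scaling (adjusted p = 0.0028), where its median of 0.23 was -0.22, and had adjusted p = 0.27 with an estimated correlation.

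Genes of the tricarboxylic acid cycle and of the respiratory chain did not differ detectably from other genes as groups. In the cycle, 6 of 18 rose and 5 fell, or 5 and 4 when adjusted over the list alone, and the group test gave adjusted p = 0.22. Among those that fell were ACO1 (-0.20 ± 0.07), LPD1 (-0.27 ± 0.06), LSC2 (-0.33 ± 0.06) and IDP1 (-0.37 ± 0.05). MDH1, the mitochondrial malate dehydrogenase gene, rose 1.81-fold and the succinate dehydrogenase genes SDH1 and SDH4 rose 1.49-fold and 1.45-fold, but the SDH1 and SDH4 calls were lost with spike-in scaling (changes of 0.12 and 0.09). The median of 0.08 was -0.11 with no scaling and -0.37 with spike-in scaling. In the respiratory chain and ATP synthase, 18 of 32 fell and 6 rose (adjusted p = 0.36). The external NADH dehydrogenase gene NDE2 rose 11.8-fold and its relative NDE1 fell 2.72-fold. CYC1, the main cytochrome c gene, fell 2.99-fold and COX5A 2.23-fold.

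Glucose and galactose uptake genes changed strongly. Of 15 hexose transporter and sensor genes, 9 rose and 4 fell, with a median of 0.60, or 0.39 after normexp background correction. HXT6, HXT7 and HXT5, transporters of low glucose or slow growth, rose 5.21-fold, 4.68-fold and 4.56-fold, and MTH1, a repressor of transporter genes, rose 4.85-fold. HXT6 and HXT7 are nearly identical, so their signals are uncertain. HXT2 (-1.72 ± 0.06), HXT1 (-1.61 ± 0.08), RGT2 (-0.40 ± 0.07) and HXT4 (-0.35 ± 0.07) fell, and HXT9 (-0.04 ± 0.06) and STD1 (-0.10 ± 0.06) did not pass. The list passed (adjusted p = 0.033), with adjusted p = 0.29 with an estimated correlation. Of 10 known Gal4 targets, 9 rose at least 2-fold, with a median of 1.87, and FUR4, the uracil permease gene, fell by 0.35 ± 0.05. GAL7 rose 22.1-fold and GAL10 17.3-fold beside GAL1 and GAL2. The list passed (adjusted p = 1.2e-05), with adjusted p = 0.27 with an estimated correlation.

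Autophagy and vacuolar protease genes rose in 17 of 22 cases, with a median of 0.64. The vacuolar mannosidase gene AMS1 rose 3.22-fold, the protease inhibitor gene PBI2 2.54-fold, the aminopeptidase gene APE3 2.46-fold and the carboxypeptidase gene PRC1 2.34-fold. ATG5 (-0.54 ± 0.06), CPS1 (-0.40 ± 0.06) and ATG7 (-0.34 ± 0.06) fell, and ATG12 (0.14 ± 0.06) and ATG17 (-0.04 ± 0.05) did not pass. The list passed (adjusted p = 9.9e-05), with adjusted p = 0.27 with an estimated correlation. Of 19 protein kinase A pathway genes, 10 rose and 3 fell, TPK3 (-0.60 ± 0.06), SCH9 (-0.42 ± 0.06) and PDE2 (-0.23 ± 0.05). The members that rose most act both ways on the pathway. BCY1, the inhibitory subunit of the kinase, rose 4.15-fold, YAK1, a kinase opposing growth, 2.13-fold, and the activators GPA2 and CYR1 2.37-fold and 1.7-fold. The CYR1 call was lost with spike-in scaling (log2 change 0.31, adjusted p = 0.061). The list passed (adjusted p = 0.025), with adjusted p = 0.37 with an estimated correlation, and its median of 0.29 was -0.16 with spike-in scaling, where it did not pass (adjusted p = 0.13).

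**Figure D3:**
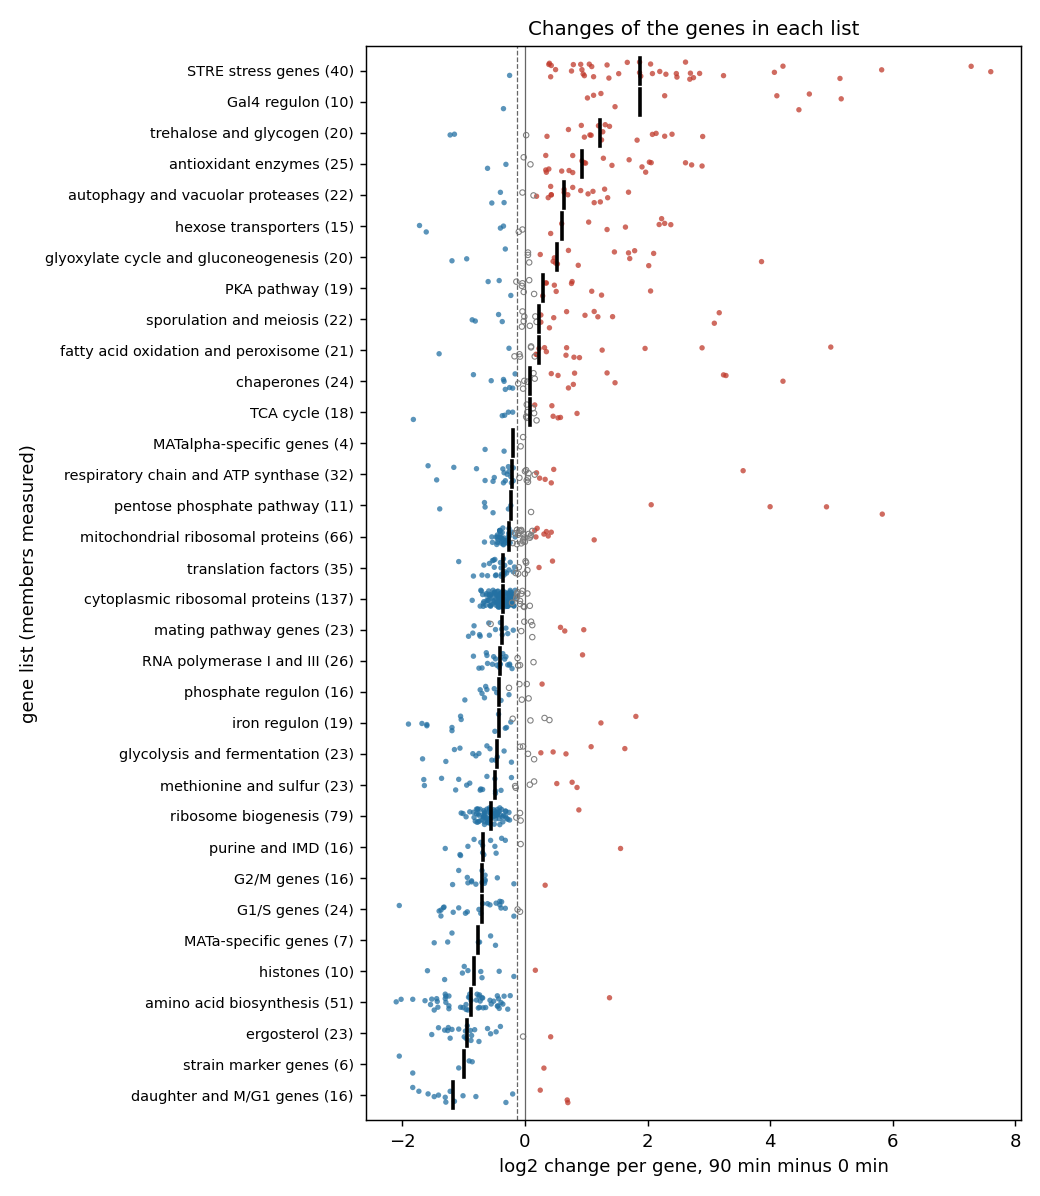
Log2 change of each measured gene (horizontal, 90 min minus 0 min) in the 34 lists (vertical, members measured in brackets), ordered by median. Red points rose, blue points fell, open points did not pass, black bars are medians, and the dashed line marks the median of all tested genes, -0.13; the medians run from -1.18 for daughter and M/G1 genes to 1.87 for stress genes.

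Genes that make ribosomes fell together by small amounts. Of 137 cytoplasmic ribosomal protein genes, 123 fell, or 125 when adjusted over the list alone, with a median of -0.36 and no member changed 2-fold. RPL22B fell 1.81-fold and RPS25B 1.66-fold. Most have a duplicate of nearly the same sequence, so single values are uncertain, and the name pattern that defined the list also took in RPP1, an RNase P subunit gene. In ribosome biogenesis, 75 of 79 genes fell, with a median of -0.56. The nucleolar genes NSR1, RRP12 and DBP2 fell 2.06-fold, 2.02-fold and 1.95-fold, and SPB4 rose by 0.88 ± 0.06. UTP22 (-0.07 ± 0.06), NOP10 (-0.08 ± 0.10) and ENP1 (-0.14 ± 0.06) did not pass. The ribosomal protein list (adjusted p = 1.6e-08) and the biogenesis list (adjusted p = 4.3e-09) both passed, each with adjusted p = 0.35 with an estimated correlation.

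RNA polymerase I and III genes fell in 21 of 26 cases, with a median of -0.40 (adjusted p = 0.0053), and adjusted p = 0.42 with an estimated correlation. The large subunit genes RPA190 and RPA135 fell 1.79-fold and 1.68-fold, and the polymerase I initiation factor gene RRN3 rose 1.91-fold, with RPA14 (0.14 ± 0.06) a second riser when adjusted over the list alone. RRN5 (-0.08 ± 0.07), RPC34 (-0.11 ± 0.09) and RPC11 (-0.12 ± 0.06) did not pass. Translation factor genes fell in 26 of 35 cases, led by the elongation factor genes EFB1 (2.12-fold) and TEF4 (1.79-fold), with TIF4632 (0.45 ± 0.08) and CAM1 (0.23 ± 0.06) higher. The median was -0.35 (adjusted p = 0.0033), with adjusted p = 0.27 with an estimated correlation. Of 66 genes taken in by a name pattern for mitochondrial ribosomal proteins, 38 fell and 8 rose, with MRPL15 1.58-fold lower. MRP8, whose place in the list rests on its name alone, was 2.19-fold higher. That list passed (adjusted p = 0.033) with a median of -0.26, had adjusted p = 0.55 with an estimated correlation, and missed the threshold without replicate 2 at 0 min (adjusted p = 0.08) or replicate 2 at 90 min (adjusted p = 0.057). It also missed it with quantile normalization (adjusted p = 0.052), no scaling (0.053), spike-in scaling (0.13) and the deposited value table (0.057).

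In amino acid synthesis 50 of 51 genes fell, 19 of them at least 2-fold, with a median of -0.88. The lysine genes LYS20, LYS9, LYS2 (3.55-fold) and LYS4 (3.09-fold) fell most, and SER3, of serine synthesis, rose by 1.38 ± 0.06. In methionine and sulfur metabolism, 16 of 23 genes fell, with a median of -0.49. The methionine synthase gene MET6 fell 3.14-fold, the methionine permease gene MUP1 3.12-fold and the S-adenosylmethionine synthetase genes SAM1 and SAM2 2.57-fold and 2.19-fold. STR3 (0.85 ± 0.07), MET28 (0.77 ± 0.06) and SUL2 (0.52 ± 0.08) rose, and MET32, MET2, MET1 and SUL1 did not pass. Amino acid synthesis passed (adjusted p = 6.7e-10), with adjusted p = 0.27 with an estimated correlation, and methionine and sulfur passed (adjusted p = 0.014), with adjusted p = 0.28 with an estimated correlation.

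Of 16 purine synthesis genes, 14 fell, with a median of -0.68, among them the IMP dehydrogenase genes IMD4 (2.47-fold) and IMD3 (2.09-fold), which are similar in sequence. ADE16 rose 2.94-fold while ADE17, which encodes its isozyme, fell 2.06-fold, and MTD1 did not pass. In ergosterol synthesis, 21 of 23 genes fell, with a median of -0.94. ERG5 fell 2.86-fold, ERG25 2.66-fold and the HMG-CoA reductase gene HMG1 2.47-fold, whereas HMG2, the other reductase gene, rose by 0.42 ± 0.06 and ERG28 had a change of -0.03 ± 0.06. The purine list passed (adjusted p = 0.0041), with adjusted p = 0.32 with an estimated correlation, and the ergosterol list passed (adjusted p = 1.2e-05), with adjusted p = 0.27 with an estimated correlation.

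Cell cycle genes of every phase tested were lower. Among G1/S genes, 22 of 24 fell, with a median of -0.70, including the ribonucleotide reductase gene RNR1 (2.58-fold), the G1 cyclin gene CLN2 (2.58-fold) and YOX1 (2.64-fold), and PRI1 and TOS4 did not pass. Of 10 histone genes, 9 fell, led by HTB2 (3-fold) and HTA2 (2.48-fold), and the linker histone gene HHO1 rose by 0.17 ± 0.06. Histone gene pairs are similar in sequence, so their single values are uncertain. Among G2/M genes, 15 of 16 fell, including the mitotic cyclin genes CLB2 (2.26-fold) and CLB1 (2.11-fold) and the polo kinase gene CDC5 (1.92-fold), and SPO12 rose by 0.33 ± 0.07. Daughter-specific and M/G1 genes had the lowest median, -1.18, with 13 of 16 fallen. The cell separation genes SCW11, DSE4, DSE2 and CTS1 fell 3.56-fold, 3.32-fold, 2.99-fold and 2.78-fold, whereas SIC1 (0.70 ± 0.05), an inhibitor of S phase kinases, RME1 (0.69 ± 0.05) and CLN3 (0.25 ± 0.06) rose. The G1/S (adjusted p = 1.2e-05), histone (adjusted p = 0.0062), G2/M (adjusted p = 0.00099) and daughter (adjusted p = 0.0067) lists passed. With an estimated correlation they had adjusted p = 0.27, 0.29, 0.27 and 0.28.

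All 7 genes specific to MATa cells fell, with a median of -0.76 (adjusted p = 0.0047), and adjusted p = 0.28 with an estimated correlation. The pheromone genes MFA2 and MFA1 fell 2.78-fold and 2.28-fold and the protease gene BAR1 2.4-fold. The 4 MATalpha-specific genes did not pass the test against other genes (adjusted p = 0.32), with SAG1 at -0.34 ± 0.06 and the alpha-factor gene MF(ALPHA)1 at -0.65 ± 0.06, or -0.35 after normexp background correction. In the mating pathway, 14 of 23 genes fell and 3 rose (adjusted p = 0.16). CIK1 fell 1.89-fold and FAR1 1.8-fold, while STE18 (0.65 ± 0.06), FUS2 (0.58 ± 0.08) and PRM3 rose, the last well above background on 3 of 4 arrays and by 0.96 on the log2 scale, or 0.31 after normexp background correction and 0.33 in the deposited value table. Of 22 sporulation and meiosis genes, 11 rose and 4 fell. SPO13 and MEK1, of meiosis, rose 9.02-fold and 8.49-fold, and IME1, the inducer of meiosis, 2.28-fold, whereas SPO11 (-0.86 ± 0.06), SPS4 (-0.81 ± 0.07), SSP1 (-0.43 ± 0.06) and SPR1 (-0.37 ± 0.08) fell. That list passed (adjusted p = 0.014), with adjusted p = 0.28 with an estimated correlation. The log2 change of MEK1, 3.09, was 2.00 after normexp background correction and 2.28 in the deposited value table. The list did not pass after quantile normalization (adjusted p = 0.22) or in the deposited value table (adjusted p = 0.16), and its median of 0.23 was 0.01 and 0.06 there and -0.22 with spike-in scaling.

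In the iron regulon, 13 of 19 genes fell, with a median of -0.43, and 2 rose, or 3 when adjusted over the list alone. FET3 fell most, the mRNA decay factor gene TIS11 fell 3.21-fold and the siderophore transporter gene SIT1 3.04-fold, whereas the reductase genes FRE2 and FRE3 rose, by 1.81 ± 0.08 and 1.24 ± 0.06. The list did not pass (adjusted p = 0.08), but did without replicate 2 at 0 min (adjusted p = 0.03), with no scaling (adjusted p = 0.042) and with spike-in scaling (adjusted p = 0.015). In the phosphate regulon, 10 of 16 genes fell, with a median of -0.42, or -0.27 after normexp background correction. The polyphosphate synthesis gene VTC2 fell 1.97-fold, PHM6 1.66-fold and the acid phosphatase gene PHO11 1.62-fold, and SPL2 rose by 0.28 ± 0.09. The log2 change of PHM6, -0.73, was -0.46 after normexp background correction. PHO11 and its copy PHO12 cannot be separated with certainty. The list passed (adjusted p = 0.038), with adjusted p = 0.28 with an estimated correlation, but missed the threshold with spike-in scaling (adjusted p = 0.084) and without replicate 1 at 0 min (adjusted p = 0.053).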

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

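Tests in this part were chosen only after the result was seen. The spike-in control probes, which entered the gene comparisons only as an alternative scaling, drew attention because their signal differed between groups. Relative to the 75th percentile of the yeast spots, their mean log2 signal was -0.47 at 0 min and -0.02 at 90 min, a difference of 0.45. It was higher at 90 min for 10 of 10 probes, by 0.41 to 0.49, against gaps of 0.24 and 0.05 between the replicate arrays of a group.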

How the results depend on the processing

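The alternatives were planned before the data were examined. Single named genes kept direction and side of the threshold in 2425 cases, lost the call in 5 and reversed in 1, URA3 (-0.14 with spike-in scaling, which by construction lowers each change by the same amount). MSN2 rose under every alternative run, by 1.71 to 2.58. Counts of genes stayed within 1.5 times the main count in 53 cases and moved further in 7. Spike-in scaling left 745 risen genes, a count that is uncertain because an offset shared by all genes of an array enters each gene's test. A log2 change of at least 1 left 786 changed genes, 548 risen and 238 fallen, and treat at 0.5 left 1429, 822 risen and 607 fallen, by construction. Without single arrays, 4174 to 4415 genes changed, 1687 to 1788 risen and 2477 to 2657 fallen, with MSN2 at 2.36 to 2.58, where the lone array is assumed to vary like the other group. With a replicate block, 4926 genes changed (1952 risen, 2974 fallen), 26 lists passed and MSN2 rose by 2.47. Deviations of arrays sharing a number correlated at r = 0.20 across genes, from 2 pairs only. List results were alike in 531 cases, gained the call in 10 and lost it in 37. With an estimated correlation 0 of 34 lists passed (limma camera, 3 at unadjusted p under 0.05). That version rests on 2 residual degrees of freedom and so has little power. The adjusted p was then 0.27 for stress, fatty acid oxidation, translation factor, amino acid, ergosterol, Gal4, autophagy, G1/S and G2/M genes, and 0.28 for trehalose and glycogen, glyoxylate, antioxidant, methionine, daughter, MATa, sporulation, phosphate and strain marker genes. It was 0.29 for hexose transporters and histones, 0.32 for purines, 0.35 for ribosomal proteins and ribosome biogenesis, 0.37 for protein kinase A, 0.42 for polymerases and 0.55 for mitochondrial ribosomal proteins. Spike-in scaling and no scaling shift all genes of an array alike, so a list keeps its place against other genes. Differences in p-value there come from how the test weighs each change by its spread, not from a shift of the list. For the other alternatives below, the cause of the change was not tested. With spike-in scaling, adjusted p was 2.6e-05 for the pentose phosphate pathway, 0.0049 for chaperones, 0.13 for mitochondrial ribosomal proteins and for protein kinase A genes, 0.015 for iron and 0.084 for phosphate. With no scaling it was 0.017 for chaperones, 0.053 for mitochondrial ribosomal proteins and 0.042 for iron. Quantile normalization gave 0.044 for chaperones, 0.052 for mitochondrial ribosomal proteins and 0.22 for sporulation, the deposited value table gave 0.057 for mitochondrial ribosomal proteins and 0.16 for sporulation, and an intensity trend gave 0.045 for chaperones. Without single arrays, adjusted p was 0.039 to 0.085 for chaperones (lowest without replicate 1 of either group), 0.02 to 0.08 for mitochondrial ribosomal proteins (highest without replicate 2 at 0 min, and 0.057 without replicate 2 at 90 min), 0.03 to 0.12 for iron (lowest without replicate 2 at 0 min) and 0.025 to 0.053 for phosphate (highest without replicate 1 at 0 min), and 25 to 27 lists passed. The promoter motif test and its alternatives on window, copies and size of change were not run. Between 98.3% and 99% of probes were well above background. The size of a change at low signal still depended on the background step, as for MSN2 (2.47 on the main scale, 1.71 after normexp) and MEK1 (3.09 and 2.00).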

Other observations

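The gene lists and tests in this part were chosen only after the results were seen, except the test of neighbouring genes. The zinc and biotin lists hold genes from the 15 largest falls, so their p-values partly restate those falls. Genes that respond to zinc through the regulator Zap1 were lower at 90 min, with 15 of 16 fallen and a median log2 change of -1.15. Besides ZPS1, ADH4, ZRT1 and YOR387C, INO1, of inositol synthesis, fell by 1.75 ± 0.06 and the low-affinity iron transporter gene FET4 by 1.41 ± 0.06, and ZRG8 rose by 0.45 ± 0.06. The list was lower than other genes (camera, adjusted p = 0.00029), with adjusted p = 0.30 with an estimated correlation. All 5 biotin genes fell, with a median of -1.49 (adjusted p = 0.0037, and adjusted p = 0.30 with an estimated correlation), and the biotin transporter gene VHT1 fell 2.6-fold. In phospholipid synthesis, 12 of 14 genes fell, with a median of -0.77 (adjusted p = 0.0036, and adjusted p = 0.23 with an estimated correlation). This list shares a member with the zinc list, so the results of both are not independent. CHO2 fell 2.46-fold and CHO1 2.13-fold, PIS1 rose by 0.58 ± 0.06 and PCT1 had a change of -0.05 ± 0.07. In fatty acid synthesis, 8 of 12 genes fell, with a median of -0.79 (adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation). The synthase genes FAS1 and FAS2 fell 2.72-fold and 2.54-fold and the desaturase gene OLE1 2.56-fold.

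Proteasome genes moved up by small amounts, with 31 of 33 risen and a median of 0.30, which was -0.15 with spike-in scaling. RPN4, the activator of proteasome genes, is counted among the 33 and rose 3.15-fold. RPN11 rose 1.49-fold, and RPN2 (0.08 ± 0.05) and RPT3 (0.13 ± 0.05) did not pass. The list was higher than other genes (adjusted p = 1e-06), with adjusted p = 0.23 with an estimated correlation. EMP46, which lies next to GAL2, rose by 3.47 ± 0.09. YBR116C, a dubious reading frame beside TKL2, rose by 3.42 ± 0.07, and whether its probe reads the TKL2 transcript was not tested. RIM8 has 2 probes that were called in opposite directions, at 1.59 ± 0.06 and -0.31 ± 0.08.

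Some isozymes of carbon metabolism, respiration and stress defence moved apart. In 15 of 20 pairs, assembled after the values were seen, both members passed the threshold in opposite directions, such as CYC7 (4.07 ± 0.06) with CYC1 (-1.58 ± 0.08) and ACS1 (1.71 ± 0.08) with ACS2 (-1.50 ± 0.06). TSA2 and TSA1 both rose, as did GRX2 and GRX1, and ENO1 and ENO2 both fell. In the pairs PDC6 with PDC1 and TDH1 with TDH3, PDC1 and TDH1 did not pass. A fall common to all genes would lower the major members by no more than the median of all genes, but their median minus that of all genes was -0.53, and 16 of 20 lay below it. Because the pairs were picked with the values in view, this comparison of the set cannot weigh such a fall as a cause. The label of major member also did not follow signal in every pair. PFK27, labelled major, had a lower log2 signal than PFK26 at 0 min (-2.91 against -1.27), as did COX5A beside COX5B (1.51 against 1.70). Single falls, such as those of CYC1 and ACS2, were larger than the median of all genes, -0.13. No biological explanation was tested.

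The rise of Gal4 targets was set against release from glucose repression. The smallest change among GAL1, GAL2, GAL7 and GAL10, 4.11 for GAL10, lay 2.09 ± 0.08 (SE) above the largest among 10 glucose-repressed genes without known Gal4 sites, 2.02 for ADH2. Of those 10 genes 7 rose and SUC2 and CYC1 fell, with a median of 0.28 that was 0.15 after quantile normalization, 0.10 in the deposited value table, 0.08 with no scaling and -0.18 with spike-in scaling (adjusted p = 0.035, and adjusted p = 0.30 with an estimated correlation). POT1, a peroxisomal gene outside that set, rose by 4.99, more than GAL10, so the gap does not exclude release from glucose repression, which remains open. An estradiol-bound activator that recognises Gal4 sites, as used in some inducible systems, may be a source, but 0 samples had estradiol without Msn2A6, so it and an effect of Msn2A6 cannot be told apart for these genes.

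Strain BY4741 is known to lack LEU2, URA3 and MET17, yet the probes of all 3 genes were well above background on 4 of 4 arrays. If the probes read their own genes, that argues against deletion of all 3 with no added copy. Probes reading transcripts of other genes remain open, as 0 probe sequences were compared. No biological explanation was tested.

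A hypothesis written before the data were examined held that divergent neighbours, which share a promoter region, change together more than convergent ones. Log2 changes correlated at r = 0.27 over 1382 divergent pairs, 0.02 over 1395 convergent pairs and 0.12 over 2585 tandem pairs, where genes are not independent replicates. The difference of 0.26 between divergent and convergent pairs had a one-sided permutation p of 1e-05, the smallest that 100000 resamples can give, which is consistent with a shared promoter region.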
